A study of Mus musculus with 2 samples.

How the data were processed

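H3K27me3, a histone methylation mark laid down by a Polycomb repressive complex, was measured by chromatin immunoprecipitation and sequencing in the midbrain of B6NCrl mouse embryos of 10.5 days. Per the labels, there was 1 group with 2 biological replicates, the first pooled from 69 embryos and the second from 51, each of mixed sex and each with technical replicates. A control experiment is named in the labels and was not used here. With 1 group, the design holds no comparison between conditions, so the comparisons are between both replicates and between classes of genes, regions and chromosomes within the tissue.

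The authors deposited 4 peak lists in mm10 coordinates, per the file headers and labels: 1 list for each replicate, 1 list for both replicates pooled, and 1 list of replicated peaks. The aligner, the peak caller and the rule for calling a peak replicated are not given in the sources used here. Each deposited list holds a signal score, a −log10 p and a −log10 q per peak. Peaks were ranked within a list by −log10 p. The −log10 q was used to filter peaks within a list and to describe classes of peaks. Peak lists hold no read counts, so the depth of each library is unknown, and no value below has a counting interval based on reads. All 69714 replicated peaks were identical in position and name to a pooled peak. Of the pooled peaks, 52563 overlapped a peak of each replicate by at least 50% of either peak, and all of these were in the replicated list. The replicated list also held peaks that this rule does not give, 17151 in number, and 16831 of its peaks (24.1%) missed at least 1 replicate list altogether. Peaks that overlapped both replicate lists held 92.0% of the replicated bases, and genome coverage, marked genes, gene lists, Hox clusters, long domains, X coverage, CpG-rich promoters and genomic context were recomputed on them.

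Gene positions were taken from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, and sequence composition from its FASTA file. The 21755 protein-coding genes on chromosomes 1 to 19 and X were used. The Y chromosome holds no peak in any list and was left out of the gene results. A gene was called marked when at least 1000 bp of the 4000 bp window around its 5' end (2 kb each side) were covered by the replicated list. A promoter was called CpG-rich when the observed over expected CpG ratio was at least 0.6 and GC content at least 50% within 500 bp of the gene start. Replicated peaks at most 3 kb apart were merged into domains, and domains of at least 10 kb were called long. Covered bases of the genome were assigned to promoter windows first, then exons, introns and intergenic sequence. Peaks of different replicates were called shared when they overlapped by at least 1 bp.

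Chance overlap came from 1000 circular shifts of one list within each chromosome, for which the smallest possible one-sided p is 0.000999 and the smallest two-sided p, used for gene lists, is 0.002. The 28 gene lists were fixed before the data were examined, and all of their symbols matched a gene. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 28 lists. CpG-rich and other promoters were compared by the same test, and X was ranked among the 20 chromosomes in an exact test with a smallest possible one-sided p of 0.05. Neighbouring genes are not independent, so the lists were also tested by circular shifts of the peaks. That planned test compared a list's marked percent with its own percent under shifts. After its result had been seen, 2 further tests were added: the same shifts with the marked percent of the list minus that of all other genes, and 10000 rotations of the marked calls along the genes in genome order. Shifted peaks mark few genes, so the difference from other genes has a floor after shifts, and a call of lower from that test is fixed by its construction and was not used. Rotations keep the number of marked genes and the runs of marked neighbours. The recomputation on peaks shared with both replicate lists and on autosomes only was also added after the data had been seen.

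Genes were named by a rule fixed in advance: in each list the 2 genes with the most covered window bases and the 1 gene with the fewest (ties went to the longer domain for the former and to fewer bases in the pooled list for the latter, then by alphabet), up to 3 genes starting in each of the 10 longest domains, and all members of the midbrain list. Other genes named in the text were chosen after their values had been seen. The alternatives were each replicate list alone, the pooled list, peaks with q below 0.01, other windows and coverage minimums, any annotated transcript start, a CpG-rich background, other merging distances, chromosome length without runs of N, and an overlap of at least 50% of the peak. The window of 1 kb each side with 500 bp covered and the minimum of 2000 bp were used for the number of marked genes. They were left out of the alternatives for the gene lists. On simulated data with 1500 promoters, 441 of 441 planted marked genes were recovered and 0 others were called, and 5.6% of 500 random gene lists passed p of 0.05. Planted genes were set above the minimum of 1000 bp and all others below it, so full recovery was fixed by construction and checks only the code. Simulated genes were marked independently of each other, so the 5.6% does not cover lists of neighbouring genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.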

Results

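H3K27me3, a histone mark of genes silenced by Polycomb, was mapped in embryonic mouse midbrain at 10.5 days, when this part of the neural tube holds dividing progenitors and its first neurons. The 2 replicates came from separate pools of embryos, 69 in the first and 51 in the second. The authors' peak list held 152654 peaks in replicate 1 and 114260 in replicate 2, with median widths of 318 bp and 331 bp. The list called on both replicates pooled held 138162 peaks, and the replicated list, on which gene and region results below rest, held 69714 peaks with a median width of 773 bp. Read depth was unknown. Where a value is given as a mean with its SD, it is over both replicate lists (n = 2).

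The first question was how much of the genome carried the mark and how far both replicates gave it. Replicate 1 covered 103.6 Mb and replicate 2 covered 79.9 Mb, a mean of 3.37% ± 0.614 of the genome (SD, n = 2), and the replicated list covered 107.7 Mb (3.95%). Both replicates covered 64.2 Mb in common, which was 62.0% of the covered bases of replicate 1 and 80.4% of those of replicate 2. Of the replicate 1 peaks 49.7% overlapped a replicate 2 peak, against a mean of 6.09% after circular shifts, and of the replicate 2 peaks 75.04% overlapped a replicate 1 peak, against 8.15%. The Jaccard index of covered bases was 0.539 against 0.0238 after shifts. Each of these values exceeded all 1000 permutation shifts (p = 0.000999, the smallest they can give).

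Sharing differed by rank of the peak. Each list was ranked by the deposited −log10 p and divided into 10 bins of equal size. In the top bin, 98.7% of replicate 1 peaks (95% Wilson interval 98.5 to 98.9) and 99.96% of replicate 2 peaks (99.90 to 99.98) were shared, and these bins held 45.9% and 45.4% of the covered bases of their lists. In the lowest bin, 22.3% (21.6 to 22.9) and 54.6% (53.7 to 55.5) were shared. From the top to the lowest bin, median width fell from 2099 bp to 217 bp in replicate 1 and from 2123 bp to 227 bp in replicate 2. Wider peaks meet the 1 bp rule more easily, and no shifted expectation was computed per bin. The intervals treat peaks as independent and do not measure variation between replicates. Replicate 1 peaks outside replicate 2 had a median width of 245 bp, against 517 bp for those that overlapped it, and the longest was 2210 bp. Of protein-coding genes, 5167 were marked at the promoter in replicate 1 and 4877 in replicate 2, and 4675 were marked in both, where independent lists would share 1158.

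**Figure D1:**
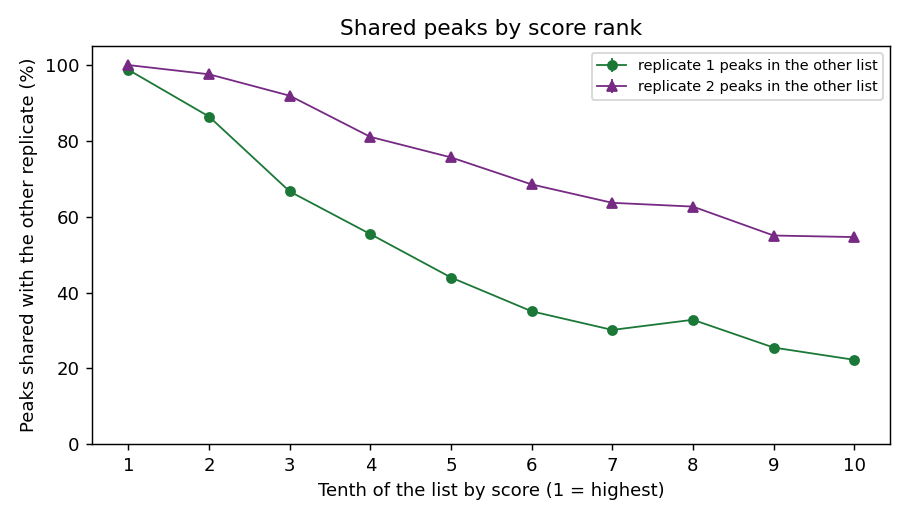
Percent of peaks of each replicate list that overlap a peak of the other list (vertical axis), in 10 bins of the list by rank (horizontal axis, 1 is highest). Peaks were ranked by the authors' −log10 p, named score on the axis. Points are shares with 95% Wilson intervals, which are smaller than most symbols; sharing fell from 98.7% to 22.3% in replicate 1 and from 99.96% to 54.6% in replicate 2.

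The replicated list marked 5628 of 21755 protein-coding genes (25.9%). Of these, 4674 were marked in both replicate lists and 355 in neither. The question for the gene lists was which classes of genes carried the mark in this tissue. Of the 28 lists, 19 were marked more often than all other genes and 3 less often. The lists share members: many Pax, LIM homeobox, T-box, forkhead, Nkx, Wnt and Fgf genes also stand in regional or tissue lists. The same marked genes therefore count repeatedly, and the 19 are not separate results. All 39 Hox cluster genes, which pattern the hindbrain, spinal cord and trunk, were marked in the replicated list and in both replicate lists (Fisher's exact test, adjusted p = 1.59e-22). These genes lay in 5 merged domains, and the exact test treats them as independent. Rotation of the calls, which keeps runs of neighbours, gave an adjusted p of 0.000622 (permutation). Hoxc10 and Hoxc11 lay in the longest autosomal domain, and all members, Hoxa1 included, were covered over the whole window of 4000 bp in the replicated list. All 28 forebrain regional identity genes were marked (exact test, adjusted p = 2.41e-16), with 28 in replicate 1 and 27 in replicate 2. Fezf2 and Lhx2, regulators of the developing cortex, were covered over the whole window within domains of 85235 bp and 77963 bp. Hesx1 had the fewest covered bases of that list, 1411 bp, and 562 bp in replicate 2 left it unmarked there. All 15 hindbrain and spinal cord genes outside the Hox clusters were marked in each list (exact test, adjusted p = 4.77e-09). Cdx4 and Tlx1 were fully covered, and Mafb was covered over 2657 bp.

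Genes of midbrain identity carried the mark in midbrain tissue as well. Of 18 genes that specify midbrain and the isthmus, its border with the hindbrain, 17 were marked in the replicated list and in each replicate list (exact test, adjusted p = 4.77e-09). Pax3 and Pax7 lay in domains of 113902 bp and 108409 bp, Lmx1b in one of 98208 bp, Dmbx1 in one of 102530 bp and En2 in one of 73857 bp. En1, Lmx1a, Pax2, Pax5, Pax8, Barhl1, Barhl2, Wnt1, Fgf8 and Fgf17 were covered over all 4000 bp of the window in the replicated list. Otx2, which is needed to form midbrain, was covered over 2532 bp in replicate 1 and 3275 bp in replicate 2. Otx1 had 1190 bp in replicate 1 and 3477 bp in replicate 2, with none of the central 1 kb covered in the replicated list. Meis2 was the 1 member that was not marked, with 486 bp covered. The central 1 kb was covered over a mean of 83.9% in replicate 1 and 91.0% in replicate 2 for the midbrain list, and over 92.3% and 93.8% for the forebrain list.

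Lists of neuronal subtypes, neurons in general and progenitors were each marked more often than all other genes, and the differences between these lists were not tested. Of 12 genes of midbrain GABAergic neurons, 11 were marked (exact test, adjusted p = 6.8e-06), among them Lhx5 and Helt, and Gad1, which encodes a GABA-synthesising enzyme, was not. Of 15 genes of ventral midbrain and dopaminergic neurons, 12 were marked (exact test, adjusted p = 3.35e-05), with 12 in replicate 1 and 11 in replicate 2. Neurog2 and Foxa2 were fully covered, and Aldh1a1 had 0 bp. Pan-neuronal genes were marked in 11 of 14 cases (exact test, adjusted p = 8.7e-05), with 10 in replicate 1 and 11 in replicate 2. Elavl3 and Ina had 4000 bp covered and Elavl4 had 0 bp. Neural progenitor genes were marked in 9 of 16 cases (exact test, adjusted p = 0.0132), with 8 in replicate 1 and 9 in replicate 2. Zic1 and Sox1 were fully covered, and Fabp7, a marker of radial glia, had 0 bp. Among the same list, chosen after the values were seen, Nes and Vim had no covered base in the replicated list and Sox2 had 2586 bp.

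Mesoderm, neural crest and endoderm lists were marked more often than all other genes, and the blood and germline lists did not pass the test. Of 26 genes of mesoderm, heart and muscle, 22 were marked in all 3 lists (exact test, adjusted p = 2.26e-09), including Tbx5 and Hand2, and Myog had 0 bp. All 11 neural crest and head mesenchyme genes were marked (exact test, adjusted p = 8.05e-07), Tfap2a and Tfap2b over 4000 bp and Snai2 over 2906 bp. Of 14 endoderm, liver and pancreas genes, 9 were marked (exact test, adjusted p = 0.0041), with Pdx1 and Hnf1b fully covered and Afp, which encodes a secreted protein of fetal liver, at 0 bp. Blood and endothelial genes were marked in 4 of 16 cases (exact test, adjusted p = 1) and in 3 of 16 in each replicate list, Kdr and Klf1 among them, and Cdh5 had 0 bp. Germline and pluripotency genes were marked in 3 of 12 cases (exact test, adjusted p = 1). The marked ones included Pou5f1 over 4000 bp and Nanog over 3235 bp, 2 regulators of pluripotency, and Dazl, a germ cell gene, had 0 bp. The other marked genes of these lists, named after their values were seen, were Hba-x, Runx1 and Tdrd1, and Runx1 was marked in neither replicate list (829 bp and 728 bp).

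In the families of developmental transcription factors and signals, all 14 Nkx genes (exact test, adjusted p = 1.66e-08), all 12 LIM homeobox genes (adjusted p = 2.27e-07, exact test) and all 9 Pax genes (adjusted p = 1.03e-05, exact test) were marked in each list. All Nkx genes had 4000 bp covered in the replicated list, and among them Nkx6-2 and Nkx2-3 lay in the longest domains, of 122331 bp and 65570 bp. Lmx1b and Lhx5 were fully covered too, and the least covered LIM homeobox and Pax genes were Lhx3 at 2749 bp and Pax4 at 2185 bp. All 19 Wnt ligands were marked (exact test, adjusted p = 3.82e-11), with Wnt3a and Wnt9a in 1 domain of 83029 bp and Wnt5a least covered at 1193 bp. Fgf ligands were marked in 15 of 22 cases (exact test, adjusted p = 6.64e-05), Fgf16 and Fgf8 fully and Fgf20 at 0 bp, with 14 marked in replicate 1 and 15 in replicate 2. Forkhead genes were marked in 32 of 44 cases (exact test, adjusted p = 4.77e-10), Foxd2 and Foxe3 in 1 domain of 62028 bp and Foxk1 at 0 bp, with 31 marked in replicate 1 and 29 in replicate 2. T-box genes were marked in 12 of 16 cases (exact test, adjusted p = 8.7e-05), Tbx3 and Tbx5 fully and Tbx6 at 0 bp. Of 7 cyclin-dependent kinase inhibitors, which hold back the cell cycle, 5 were marked (exact test, adjusted p = 0.0191). Cdkn2a and Cdkn2b shared 1 domain of 49663 bp and Cdkn2d had 0 bp. Cdkn2c, Cdkn1c and Cdkn1a, named after their values were seen, were marked as well. Against CpG-rich promoters alone, 4 of 6 were marked and the adjusted p was 0.0963 (exact test). Over the alternatives used for gene lists, adjusted p ranged from 0.00266 (circular shifts) to 0.0963 (exact test).

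Cell cycle genes, olfactory receptors and Zfp genes were marked less often than all other genes. None of 17 cell cycle genes was marked in any list (exact test, adjusted p = 0.0136), and Aurkb and Bub1 had 0 bp. Of 1135 olfactory receptor genes 3 were marked (exact test, adjusted p = 3.59e-144), among them Olfr95 and Olfr94, and Olfr94 was unmarked in both replicate lists. The remaining one, Olfr550, was named after its values were seen. Of 365 Zfp genes, many of which encode KRAB zinc finger repressors, 30 were marked, or 8.22% against 26.2% of all other genes (exact test, adjusted p = 6.84e-17). Zfp365 and Zfp853 were fully covered and Zfp1 had 0 bp. With circular shifts of the peaks the comparison was with a random placing of the mark, under which 5.64% of Zfp genes would be marked. The Zfp list did not pass that test (permutation, adjusted p = 0.116). Nor did the cell cycle list (permutation, adjusted p = 0.827), of which shifted peaks marked 5.09%. Its count of 0 is the lowest possible, so that test could not have called it lower. Rotations of the calls along the genes left the Zfp and cell cycle lists lower (permutation, adjusted p = 0.00035 and 0.0162). The exact test of the olfactory receptors treats neighbouring genes as independent. By rotation that list was lower too (permutation, adjusted p = 0.00035, from the smallest p the rotations can give). Over the alternatives used for gene lists, adjusted p ranged from 7.71e-18 (exact test) to 0.116 (circular shifts) for the Zfp list. For the cell cycle list it ranged from 0.00197 (exact test) to 0.827 (circular shifts, which could not call that list lower).

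Other lists did not pass Fisher's exact test. Housekeeping genes were marked in 3 of 18 cases (exact test, adjusted p = 0.661), with 1 marked in replicate 1 and 2 in replicate 2. Pgk1, an X-linked glycolysis gene, had 2924 bp, B2m had 1155 bp and Actb, named after its values were seen, had 1118 bp, and Eef1a1 had 0 bp. B2m had 909 bp and 556 bp in replicates 1 and 2 and was marked in neither. Polycomb complex members were marked in 8 of 22 cases (exact test, adjusted p = 0.382). Phf19 had 3928 bp and Cbx8 had 3248 bp, while Cbx7 had 0 bp. This list passed as higher with any overlap of 1 bp (exact test, adjusted p = 0.015) and against a random placing of the peaks by circular shifts (permutation, adjusted p = 0.00266). It did not pass by the same shifts against other genes (permutation, adjusted p = 0.13) or by rotation (permutation, adjusted p = 0.44). Over the alternatives used for gene lists, adjusted p ran up to 0.681 (exact test). Clustered protocadherins, adhesion proteins that give neurons individual surface identities, were marked in 13 of 57 cases (exact test, adjusted p = 0.703), with Pcdhgc5 and Pcdhac2 fully covered and Pcdha1 at 0 bp. This list was higher against CpG-rich promoters, with 3 genes left (exact test, adjusted p = 0.038), and against a random placing of the peaks, which marked 4.05% of it (permutation, adjusted p = 0.0483). Against other genes the same shifts gave an adjusted p of 0.925 and rotation 0.875 (permutation). Keratins were marked in 7 of 49 cases (exact test, adjusted p = 0.0875), Krt8 and Krt18 over 4000 bp and Krt10 at 0 bp.

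**Figure D2:**
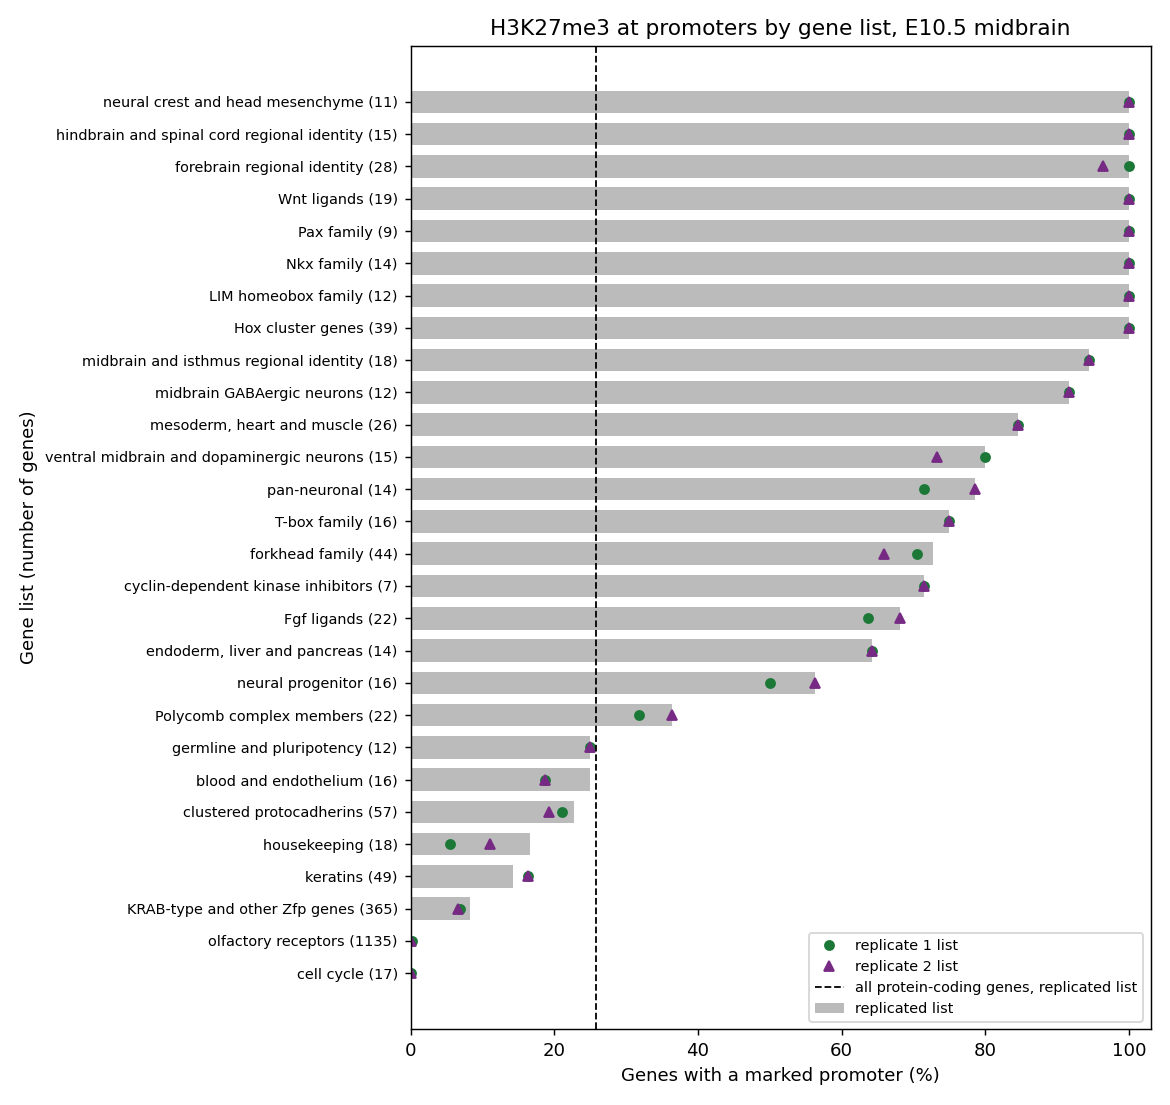
Percent of genes with a marked promoter (horizontal axis) in each of the 28 gene lists, with the number of genes in parentheses. Bars show the replicated list, circles replicate 1, triangles replicate 2 and the dashed line all protein-coding genes (25.9%). Regional identity, Hox, Pax, Nkx, LIM homeobox, Wnt and neural crest lists lie at or near 100%. Midbrain GABAergic neuron genes lie at 91.7% and cell cycle genes at 0.

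The Hox clusters were examined as regions known to be bound by Polycomb. From the first to the last Hox gene, Hoxa (chromosome 6, 52155590 to 52260880, mm10) was covered over 99.94% ± 0.0846 of its length (SD, n = 2), Hoxc (chromosome 15, 102921103 to 103036852) over 100% in both replicates, and Hoxd (chromosome 2, 74668310 to 74765142) over 99.6% ± 0.0869 (SD, n = 2). In the replicated list 1 peak spanned each of Hoxa and Hoxc. Hoxb (chromosome 11, 96194316 to 96368256) was covered over 85.4% ± 0.00569 (SD, n = 2). Its longest uncovered stretch in the replicated list ran over 13.9 kb from 96218375 to 96232268, in the interval between Hoxb13 and Hoxb9, and both replicate lists held short peaks within it.

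**Figure D3:**
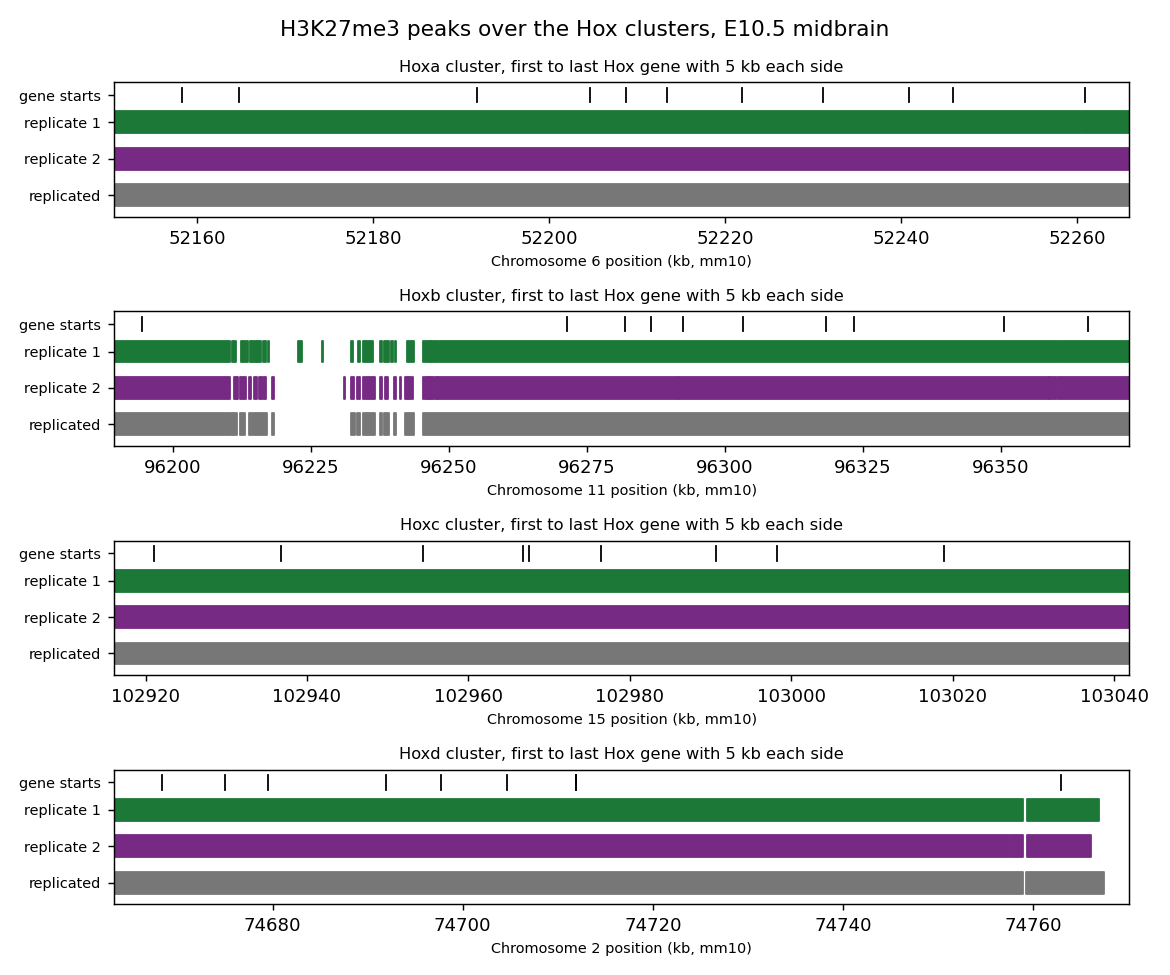
Peaks of both replicate lists and the replicated list (bars) along the 4 Hox clusters, with gene starts as ticks; the horizontal axis is chromosome position in kb (mm10). In the replicated list coverage is unbroken over Hoxa and Hoxc, and Hoxb has an uncovered stretch of 13.9 kb between Hoxb13 and Hoxb9, in which both replicate lists hold short peaks.

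Merging the replicated peaks gave 22978 domains with a median length of 2567 bp. Long domains, of at least 10 kb, numbered 3390 and held 62.7% of the covered bases, and 302 domains reached 50 kb. With peaks merged over at most 1 kb in place of 3 kb, 2250 domains were long. A protein-coding gene started in 1389 of the long domains. The 10 longest were all on X. The longest, 565.6 kb from 99112757 to 99678402, was covered over 93.4% in replicate 1 and 91.7% in replicate 2 and held the starts of Efnb1, which encodes a membrane ligand of Eph receptors, and Pja1. The next, 563.8 kb from 140329971 to 140893782, held 5 starts, Frmpd3, Prps1 and Tsc22d3 among them. Others held those of Rai2 (356.6 kb), Nhsl2 and Rtl5 (274.7 kb), Hsd17b10, Ribc1 and Smc1a among 4 genes (272.1 kb), Rnf138rt1 (267.1 kb) and Map3k15 (262.0 kb), and 3 held no protein-coding start. Of the 100 longest domains 67 were on X, which makes up 6.49% of the length of chromosomes 1 to 19 and X. The longest autosomal domain, 260.4 kb on chromosome 15, spanned the Hoxc cluster.

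The tissue was pooled from both sexes, and in females 1 X chromosome is silenced and carries H3K27me3, so X was compared with the autosomes. Peaks covered 11.1% of X in replicate 1 and 9.58% in replicate 2, against autosome medians of 3.32% and 2.51%. In the replicated list X was covered over 12.4% and the 19 autosomes over 2.12% to 6.04% with a median of 3.44%, a ratio of 3.60. X ranked highest of 20 chromosomes in each list (exact test, one-sided p = 0.05, the smallest the design allows), and the ratio was 3.34 in replicate 1 and 3.82 in replicate 2. Of 948 X-linked genes 325 were marked (34.3%), against 25.5% of 20807 autosomal genes (Fisher's exact test, two-sided, odds ratio 1.53, p = 4.64e-09). That test treats neighbouring genes as independent, and X did not rank highest by this measure, since on chromosome 15 35.03% of genes were marked. The mean covered share of gene bodies was 18.6% on X against 8.40% on autosomes in replicate 1, and 16.8% against 7.52% in replicate 2.

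**Figure D4:**
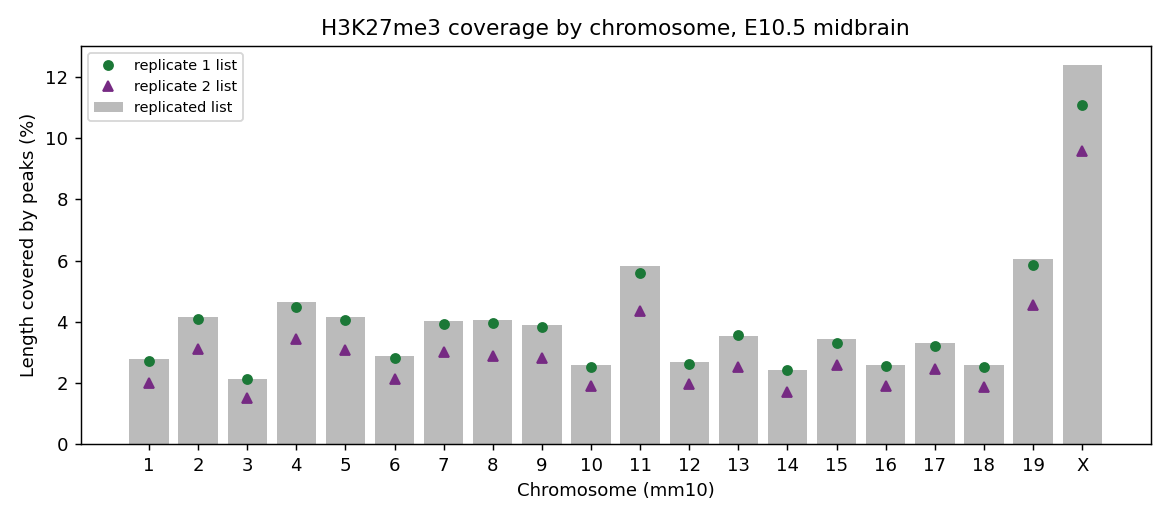
Percent of each chromosome's length covered by peaks (vertical axis) on chromosomes 1 to 19 and X. Bars show the replicated list, circles replicate 1 and triangles replicate 2; X was covered over 12.4% and the most covered autosome, chromosome 19, over 6.04%.

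The last comparisons asked which kinds of sequence carried the mark. Of 9739 genes with a CpG-rich promoter 3051 were marked (31.3%), against 2577 of 12016 others (21.4%; Fisher's exact test, two-sided, odds ratio 1.67, p = 3.16e-61). On X alone the shares were 48.0% and 29.96% (Fisher's exact test, odds ratio 2.16, p = 9.07e-07). Both tests treat neighbouring genes as independent. The 12016 others include all 1135 olfactory receptor genes, of which 3 were marked, and their part in the difference was not separated. Promoter windows made up 3.07% of the genome and 15.2% of the covered bases, a 4.96-fold excess, with 4.68-fold in replicate 1 and 5.70-fold in replicate 2. Exons were covered 1.64-fold, introns 1.03-fold and intergenic sequence 0.742-fold relative to their share of the genome. Of all covered bases 44.0% were intergenic and 35.7% intronic.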

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

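The test of weak peaks on X and the tests of single housekeeping genes were chosen after the result had been seen. The pooled list held 68448 peaks that are not in the replicated list. They were picked out because peaks are present outside the list on which the gene and region results rest, and they enter those results only where the pooled list is named as an alternative. They covered 21.9 Mb with a median width of 282 bp and a median −log10 q of 2.85, against 773 bp and 6.89 for the pooled peaks in the replicated list. Of them 30590 overlapped replicate 1 alone, 12578 replicate 2 alone, 542 both and 24738 neither. On X lay 10.3% of them, against 19.3% of the peaks in the replicated list.

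X was covered 3.60 times as much as the median autosome. X has the fewest CpG-rich promoters per Mb (1.33), and the line through the 19 autosomes, extended below their range, gave 1.08% for X, 22.6 residual SD under the observed 12.4%; promoter density points to low coverage of X and was no candidate for an excess. With peaks of q below 0.01 the ratio was 3.44 in replicate 1 and 3.97 in replicate 2, which argues against weak peaks. The inactive X of female embryos predicted X above every autosome in each list, and the lowest ratio of X to the most covered autosome was 1.90. The inactive X may account for the excess, as a hypothesis; a different copy number of X in sample and control stays open, since no read counts were used here.

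Midbrain identity genes carried the mark in the tissue they specify. A mark that lies beside the gene start and spares it would give a low coverage of the central 1 kb. The midbrain median of 100% argues against such sparing across the list. The forebrain median was also 100%, the highest possible, so their ratio of 1 cannot show a partial sparing. Means were 87.3% and 93.8% (permutation p = 0.362), and a test that does not pass is no evidence of equal coverage. Otx1 and Meis2 had 0 bp of the central 1 kb covered. With the window of 1 kb each side and 500 bp covered, 17 of 17 marked genes stayed marked. Each marked gene had at least 2820 bp of its 4000 bp window covered in the replicated list. More than 500 bp therefore had to lie in the smaller window, so this result was fixed and does not decide on a wide window. The median central coverage of 100% argues against a wide window across the list, but not for Otx1. With q below 0.01 in both replicate lists 16 of 17 stayed marked, all but Otx1, which argues against weak peaks for these 16. No biological explanation was tested: in a tissue of many cell types the mark could lie in cells that do not express these genes, and the peak lists hold no expression.

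Of 18 housekeeping genes 3 were called marked. With q below 0.01 in both replicate lists 1 of the 3 stayed marked, Pgk1, which lies on X, and this argues against weak peaks for it. The replicated peaks behind the B2m and Actb calls had −log10 q values of 7.52 and 9.21, above the median of 6.89 of the replicated list. These q values come from the call on both replicates pooled, and the criterion was set after they had been seen. It therefore does not decide on weak peaks for B2m and Actb. The filter of q below 0.01 removed no covered base of either gene in the replicate lists, so it does not decide either. The weakest replicated peak behind the Pgk1 call had 5.42, below that median, so neither criterion was met by all 3 genes. In the replicate lists B2m had 909 bp and 556 bp and Actb 0 bp and 1412 bp, so neither was marked in both. Central coverage was 0 bp for B2m in the replicated list and in both replicate lists, so its call lies beside the gene start, as a wide window would give. It was 416 bp for Actb and 603 bp for Pgk1 (451 bp and 563 bp in the replicate lists), which leaves the wide window open for Actb and Pgk1.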

How the results depend on the processing

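The recomputation on autosomes only, on peaks that overlap both replicate lists, by shifts of list minus other genes and by rotation was chosen after the data had been seen. In the alternatives run for each, replicate overlap stayed above shifted lists, X ranked highest and CpG-rich promoters were marked more often; the number of marked genes stayed within 1.5 times that of the replicated list. In single replicates, the pooled list, q below 0.01, the wider window, any transcript start, autosomes only, peaks in both replicate lists and rotations, 19 gene lists were higher and 3 lower, as in the replicated list. For gene lists, the q filter ran on the replicated list and kept 69272 of its 69714 peaks. Agreement under that filter was nearly fixed in advance. The Polycomb list passed with any overlap of 1 bp (adjusted p 0.015) and under circular shifts (0.00266), not by shifts against other genes (0.13) or rotation (0.44; up to 0.681 elsewhere). Cyclin-dependent kinase inhibitors did not pass against CpG-rich promoters (0.0963), and keratins and olfactory receptors had no CpG-rich member to test. Clustered protocadherins were higher against CpG-rich promoters (0.038, 3 genes left) and against the random placing of plain shifts (0.0483), which is no comparison with other genes; shifts against other genes gave 0.925 and rotation 0.875. Under shifts Zfp genes turned to higher without passing (0.116), where shifted peaks marked 5.64% of them. Cell cycle genes gave 0.827 under shifts, where shifted peaks marked 5.09% of them. Their count of 0 could not be called lower by that test, so this is no sign of a weaker result. With list minus other genes, housekeeping genes and keratins gave 0.00243 each, which says nothing about them: shifted differences cannot fall below about -6.76, since shifted peaks mark few genes, and rotation, which keeps the real rate, gave 0.63 and 0.379.

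Requiring 50% overlap lowered sharing in the top bin to 93.4% and 99.6% and in the lowest to 14.3% and 42.3%. Coverage of the genome was 2.93% to 3.80% in single replicates and 4.75% in the pooled list. In single replicates Hoxa was covered over 99.88% to 100%, Hoxb over 85.37% to 85.38% (pooled 88.2%, peaks in both lists 86.7%) and Hoxd over 99.50% to 99.63%. Merging at 1 kb gave 2250 long domains. Single replicates gave 4.68- to 5.70-fold for promoters, 1.60- to 1.78-fold for exons and 0.715- to 0.749-fold for intergenic sequence (pooled 0.767). The cause of these changes was not tested. Among the genes named by rule, calls were lost for B2m, Hesx1 and Olfr94 in replicate 2 and for B2m and Olfr94 in replicate 1. Leaving out a replicate leaves no overlap to compute. Unknown depth limits every statement that a region is unmarked.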

Other observations

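The groupings and tests in this part were all chosen after values had been seen. The clustered protocadherins on chromosome 18 were counted by cluster, without a test. The 22 beta genes held 0 marked members, the alpha cluster 2 of 14 and the gamma cluster 11 of 21. The 5 C-type genes, which lie at the ends of the alpha and gamma clusters and are counted within them, were all marked in both replicate lists. The 2 marked alpha genes were both C-type.

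On the autosomes the longest domains were the Hoxc domain, a domain of 242.4 kb on chromosome 4 with the starts of Prdm16 and Actrt2, the Hoxa domain of 198.1 kb that also held Evx1, a domain of 166.0 kb on chromosome 7 with Dbx1 and Htatip2, and the Hoxb domain of 153.2 kb. Prdm16 and Dbx1 encode transcription factors of neural progenitors.

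The hypothesis was that genes known to escape X inactivation lack the mark, if the inactive X carries it. None of 6 such genes (Kdm5c, Kdm6a, Eif2s3x, Ddx3x, Pbdc1 and Utp14a) was marked, against 109 of 222 other X-linked genes with CpG-rich promoters, which 5 of the 6 also have (49.1%; Fisher's exact test, two-sided, p = 0.0301, and 0.0602 after Benjamini-Hochberg adjustment over the 2 tests, which does not pass 0.05). The threshold had been set on the p without adjustment and was applied to the adjusted p after both had been seen. The mean covered share of the gene body was 18.1% against 29.8% with permutation p = 0.461, before and after adjustment. Kdm6a, Utp14a, Eif2s3x and Ddx3x had 0% of the body covered in the replicated list, Kdm5c 24.6% and Pbdc1 83.8%. The 272.1 kb domain with Smc1a ended at 152231048, ahead of the Kdm5c start at 152233020, and this edge had been seen before the list was drawn up. Neither test decides the hypothesis.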
